A study of Zea mays with 2 samples.

How the data were processed

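Messenger RNA was sequenced from endosperm of maize (Zea mays) kernels collected 12 days after pollination, in 1 library labelled dek40 and 1 library labelled wild type. The endosperm is the tissue of the kernel that stores starch and protein, and the name dek stands for the defective kernel class of mutants. The sample labels and genotype entries name dek40, while the series title and its design text name dek41. The sample labels were used here, and the mutant library is called the library labelled dek40. Per the labels' protocols, RNA was extracted with Trizol, cleaned up and treated with DNase I on RNeasy columns, and libraries followed the standard Illumina procedure. The kernel source and the endosperm tissue entry are both given, and how the endosperm was separated from the embryo is not given in the sources used here.

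The submitters' processing notes name Bowtie2 2.1.0, a read aligner, and the maize genome build B73 RefGen v3. The read counting, the gene annotation and any filter on genes are not given in the sources used here. The authors deposited 1 value per gene and library, headed RPKM (reads per kilobase of gene, scaled to the mapped reads) for the library labelled dek40. The authors deposited the wild-type values under the heading FPKM (fragments per kilobase, scaled likewise), per the file headers. Both files listed the same 41406 genes, and 0 of them had a value of 0 in either file. Genes read in 1 library alone are therefore not analysed here.

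The effective depth was worked out from the values. For all 41406 genes the ratio of the deposited values equalled a fraction of whole numbers times a single constant, 1.1020, within a relative tolerance of 1e-12. The ratios would take this form whether a column counted reads or fragments. They therefore do not show that the differently headed columns hold the same unit. The implied library totals were 15669149 for the wild type and 14218436 for the library labelled dek40, up to a common factor. Whether these are reads or read pairs was left open. The smallest pair of whole reads that gives each gene's ratio was used as a lower bound of its reads, and the length implied by them is a lower bound of the gene's length. These smallest reads summed to 86.5% of the wild-type total and 86.3% of the total of the library labelled dek40. No count test was run on them. They served for exact Clopper-Pearson 95% intervals of each ratio, which cover counting error only and are at least as wide as the true counts would give. Intervals are for the ratio without a pseudocount, so for a low gene the log2 ratio with a pseudocount can lie nearer to 0 than its interval.

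As deposited, the median gene at 1 or more in both libraries (25115 genes) was 1.34-fold higher in the library labelled dek40, a log2 ratio of 0.42. The dek40 values were therefore multiplied by 0.747, so that this median is 0, and all ratios are relative to it. The log2 ratio of a gene is log2 of the scaled dek40 value plus a pseudocount of 1, minus log2 of the wild-type value plus 1, which understates the difference of low genes. A gene was called higher or lower when it differed by 2-fold or more on that scale and reached a level of 1 in at least 1 library after scaling. With 1 library per genotype there is no replicate spread, no test and no p-value, so higher and lower describe these libraries only.

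Gene lists (26) were fixed before the data were examined, by symbols and words in gene descriptions: zeins, starch synthesis, endosperm transcription factors, markers of the basal transfer layer, the embryo-surrounding region, the aleurone and the embryo, photosynthesis, alternative respiration, respiratory complexes, mitochondrial chaperones and import, pentatricopeptide repeat proteins, heat shock proteins, endoplasmic reticulum folding, glutathione S-transferases, peroxidases with catalases and superoxide dismutases, fermentation, sugar transport, cell division, core histones, cytosolic ribosomal proteins, auxin, defence proteins, NAC factors, WRKY and ethylene-responsive factors, and programmed cell death proteases. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. Its percentile describes these libraries and is not a p-value. The range beside a median is the 95% binomial interval over the list's members, or their full range where the list is too short for one (embryo-surrounding region and alternative respiration). Members that the matching rule took by mistake stayed in the lists and are named where they matter.

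Names came from the deposited descriptions and from a RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, in which 16688 of the 41406 identifiers matched. The build differs from that of the files, so no coordinates are given. Of all genes, 20161 had no description and 928 fell in a list. The rule for named genes was set before the data were examined: any gene with the symbol dek40 or dek41, and the 10 highest and 10 lowest ratios among described genes at 10 or more in a library. It also took up to 4 of each list's most abundant members with its 2 highest and 2 lowest ratios, and the 5 most abundant genes of each library. Other named genes were chosen after their values were seen, either because a list had few members past 2-fold or because they stood out.

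The calculation was tested on simulated data. The wild-type library was drawn against itself with 200 of 36433 genes changed. Of genes changed 4-fold, 96.0% of those raised and 91.3% of those reduced passed the 2-fold rule. For 2-fold changes, which sit on the rule, it was 34.0% and 29.17%. Of 26991 unchanged genes, 271 passed it. The simulated libraries differed in these genes by counting error alone, so this rate leaves out variation between kernels and libraries. The library totals were recovered exactly, and the interval held the true ratio for 96.83% of genes.

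Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, the values as deposited, upper-quartile and trimmed-mean scaling, scaling without the zeins, no minimum level, a minimum level of 5, and a 4-fold rule. Alternatives added later were a counting interval that excludes equal levels, recovered reads as a share of the implied totals, and lists without mistaken or doubtful members. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.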

Results

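The data comprised 2 endosperm RNA libraries of maize kernels at 12 days after pollination, 1 labelled dek40 and 1 labelled wild type. The values of 41406 genes were compared, and 28178 genes reached a level of 1 in at least 1 library. The implied totals were 15669149 for the wild type and 14218436 for the library labelled dek40, with medians of at least 69 and 89 reads per gene reaching that level. Levels are given as deposited (RPKM for dek40, FPKM for the wild type), while log2 ratios are dek40 over wild type after scaling to a median gene ratio of 0. There was no replicate of either genotype, so each difference is between these libraries and has no replicate check.

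The comparison asked how the endosperm transcriptome of the mutant differed from the wild type. The endosperm of the library labelled dek40 held far less storage protein mRNA: all 23 genes of the zein list were lower, with a median log2 ratio of -3.20. Of the 13 genes in the list of the basal transfer layer, the cells through which the maternal plant feeds the kernel, 10 were lower. Of 31 starch synthesis genes 11 were lower (5 as deposited), among them wx1 by 7.47-fold. The gene sh2 was lower by 2.39-fold after scaling and by less than 2-fold as deposited. In contrast, an alternative oxidase gene was 29.4-fold higher, and 11 of 21 glutathione S-transferase genes, 7 of 30 mitochondrial chaperone and import genes, 5 of 23 cell division genes and 8 of 69 core histone genes were higher.

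By the 2-fold rule, 1784 genes (6.33%) were higher and 1406 (4.99%) were lower in the library labelled dek40. At 4-fold the counts were 177 higher and 223 lower. The balance of directions depends on the scaling: 55.9% of the genes past 2-fold were higher after scaling, against 84.7% with the values as deposited. The symbol dek40 belongs to GRMZM2G019538 in the gene table, which in published work encodes a chaperone for the assembly of the proteasome. The name has also been published for a mitochondrial pentatricopeptide repeat protein, so this need not be the gene of the label. It stood at 32 RPKM in the library labelled dek40 and 19.6 FPKM in the wild type, a log2 ratio of 0.28 with a counting interval of -0.02 to 0.60. The kind of allele is not given in the sources used here, so the level of this transcript does not check the label.

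**Figure D1:**
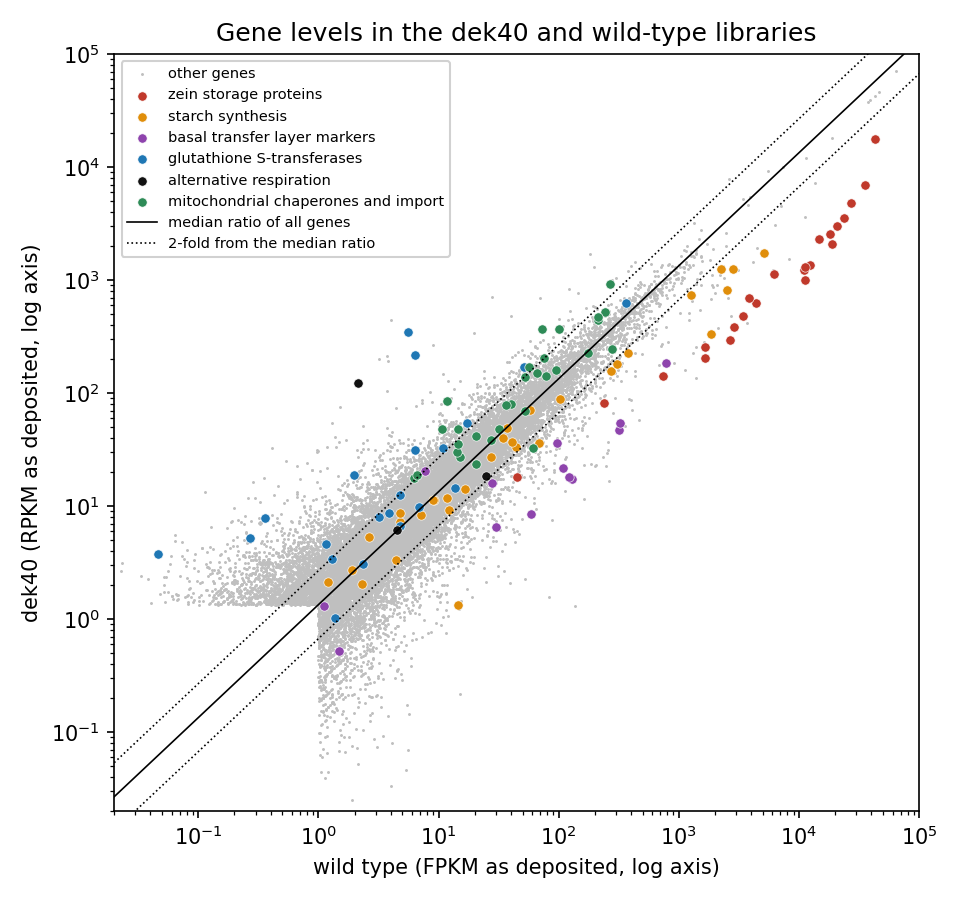
Level of each gene in the wild-type library (horizontal axis, FPKM as deposited, log axis) and in the library labelled dek40 (vertical axis, RPKM as deposited, log axis), 1 point per gene at a scaled level of 1 or more in at least 1 library, with members of selected gene lists in colour. The zein genes lie below the line of the median ratio at the high end of the wild-type axis, and the alternative oxidase gene at 2.13 FPKM and 122 RPKM lies far above it.

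Zeins are the storage proteins of the maize endosperm. They made up 19.1% of the summed FPKM of the wild type and 3.75% of the summed RPKM of the library labelled dek40. The range of the list median was -3.44 to -2.87, and its percentile among random lists was 0.00. The gamma-zein gene gz27 (GRMZM2G138727), the most abundant of them, was at 42888 FPKM in the wild type and 17551 RPKM in dek40, a log2 ratio of -1.71. The beta-zein gene zp15 (GRMZM2G086294) had a log2 ratio of -2.77, and zp16 (GRMZM2G060429) one of -2.93. The gamma zein gz50 (GRMZM2G138689), which was among the 10 lowest ratios and outside the list, was at -3.59. The lowest ratio of the list was -3.89, for Zein-alpha A30 (GRMZM2G353268), which was at 11192 FPKM in the wild type and 1007 RPKM in dek40. The fl4 gene (GRMZM2G353272), an alpha zein, had a log2 ratio of -3.53. One of the 23, Floury1 (GRMZM2G094532), is a membrane protein of the protein bodies and not a zein, and without it the median was -3.21. Alpha zeins are near-identical copies that share reads, so the split between single copies is uncertain.

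In the starch list 20 of the 31 measured genes stayed within 2-fold and 0 were higher, with a median log2 ratio of -0.60 (-1.19 to -0.17, percentile 0.00). The granule-bound starch synthase wx1 (GRMZM2G024993), which makes amylose, had a log2 ratio of -2.90, from 1848 FPKM to 330 RPKM. The subunits of ADP-glucose pyrophosphorylase, the enzyme that supplies the precursor of starch, had log2 ratios of -1.61 for bt2 (GRMZM2G068506) and -1.26 for sh2 (GRMZM2G429899). The ADP-glucose transporter bt1 (GRMZM2G144081) was at 2497 FPKM and 815 RPKM, a log2 ratio of -2.03. One of the 11 lower genes, androgenic embryo1 (GRMZM2G039942), shares the symbol ae1 with a branching enzyme and has no known part in starch synthesis. Leaving out it and 3 brittle stalk genes gave 10 of 27 lower and the same median. With the values as deposited, 5 of 31 genes of the list were lower and the median was -0.20. Those 5 include androgenic embryo1 and leave out sh2, which was at -0.84 as deposited.

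In the list of sugar transport and sucrose cleavage, 2 of 16 genes were lower and 1 was higher, with a median of -0.15 (-0.78 to 0.57, percentile 15.15), against 2 lower and 3 higher as deposited. The sucrose synthase gene sh1 (GRMZM2G089713), also in the starch list, was at 5101 FPKM in the wild type and 1740 RPKM in dek40, a log2 ratio of -1.97. The cell wall invertase mn1 (GRMZM2G119689), which cleaves incoming sucrose in the basal transfer layer, had a log2 ratio of -3.03. Another cell wall invertase, incw1 (GRMZM2G139300), was the higher one at 1.99 and was chosen after its values were seen.

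Among 7 endosperm transcription factors 3 were lower and 0 were higher, with a median of -0.84 (-1.36 to 0.18, percentile 0.17). The median was -0.23 as deposited, -0.27 with a pseudocount of 5 and -0.39 with the zeins left out of the scaling. Opaque-2 (GRMZM2G015534), an activator of zein genes, had a log2 ratio of -1.36, from 310 FPKM to 161 RPKM. The prolamin-box binding factor PBF (GRMZM2G146283), another activator of zein genes, was at -1.21. A further entry with the symbol PBF (GRMZM2G146267) was at -0.16, so the 7 genes count this symbol more than once. Nkd2 (GRMZM5G884137) was at -0.24 and ohp2 (GRMZM2G007063) at 0.18. Nkd1 (GRMZM2G129261), a regulator of aleurone cell fate, was at -1.04. With the values as deposited 0 genes of the list were lower by 2-fold, and opaque-2 was at -0.94. The list also took mrpa1 (GRMZM2G113203) through the shared symbol MRP1, at 1.48 FPKM and 0.524 RPKM, and without it the median was -0.64.

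The basal transfer layer list had a median of -2.49 (-3.09 to -0.84, percentile 0.00), with 0 of 13 genes higher, against 9 lower, 1 higher and a median of -2.07 as deposited. This list too took mrpa1 (-0.84) through the symbol MRP1, and without it 10 of 12 genes were lower, with a median of -2.58. The antifungal protein gene betl2 (GRMZM2G152655) was at 776 FPKM in the wild type and 184 RPKM in dek40, a log2 ratio of -2.49. The marker genes betl4 (GRMZM2G073290) and betl10 (GRMZM2G091445) had log2 ratios of -3.22 and -3.15. A gene with the symbol betl-9 (GRMZM2G087413), outside the list, had one of -3.76. The other side of the list was bap-3a (GRMZM2G133382), at 0.88 with a counting interval of 0.38 to 1.58. Both measured markers of the embryo-surrounding region, the endosperm next to the embryo, were lower. They were esr6 (GRMZM2G048353), at -2.12, and esr2 (GRMZM2G315601), at -1.93, with a list median of -2.03 and a percentile of 0.18.

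Markers of the aleurone, the outer endosperm layer, had a median of 0.04 (-1.04 to 0.65, percentile 56.97) and Nkd1 as the 1 lower gene of 6, against 2 of 7 higher, 0 lower and a median of 0.48 as deposited. The list was set to hold al9, but the matching missed a gene described as AL-9 protein (GRMZM2G091054). That gene, chosen after its values were seen, was higher at 1.16, from 2607 FPKM to 7778 RPKM. Embryo markers were lower in 7 of 18 cases, with a median of -0.67 (-1.30 to 0.31, percentile 0.01), against 3 of 18 lower, 3 higher and a median of -0.32 as deposited. The oleosin gene ole17 (GRMZM2G480954) was at -1.30 and Globulin-1 (GRMZM2G067919) at 0.31. The gene glb3 (GRMZM2G410134), at -1.42, was matched by the word globulin and is also described as an alpha globulin. At 2216 FPKM in the wild-type endosperm, against 28.1 FPKM for Globulin-1, it need not be an embryo marker. The 1 higher member, a non-symbiotic hemoglobin (GRMZM2G067402, 1.77), shares the symbol GLB1 and is not an embryo marker. Photosynthesis genes, a sign of green maternal tissue, had a median of -0.16 (-1.66 to 0.68, percentile 15.87) over 11 genes at low levels, with 3 lower and 1 higher. The median was 0.24 as deposited and -1.50 at a minimum level of 5. The lower ones were a photosystem II W protein (AC190623.3_FG001, -2.28), a photosystem II Z protein (GRMZM2G414660, -1.34) and a chlorophyll-binding protein (GRMZM2G038519, -1.66). The higher one was cab-m1 (GRMZM2G351977, 1.17).

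Alternative oxidase takes electrons from ubiquinone in mitochondria and bypasses the cytochrome pathway. Its gene aox2 (GRMZM2G125669) was at 2.13 FPKM in the wild type and 122 RPKM in dek40, a log2 ratio of 4.88 on at least 33 and 1711 reads. The counting interval without a pseudocount was 4.92 to 5.96. The other alternative oxidase genes were at -0.78 (GRMZM2G102349) and 0.02 (GRMZM2G010555), so the list of 3 had a median of 0.02 (-0.78 to 4.88, percentile 51.25), against 0.37 as deposited and 2.05 at a minimum level of 5. The list of mitochondrial chaperones and import had 7 of 30 genes higher and 1 lower, with a median of 0.67 (0.41 to 0.98, percentile 100). As deposited, 19 of 30 were higher and 0 lower, with a median of 1.08. The chaperonin CPN60-2 (GRMZM2G416120), which folds proteins in the mitochondrial matrix, was at 72.8 FPKM and 366 RPKM, a log2 ratio of 1.89. An inner membrane translocase subunit of the TIM14 type (GRMZM2G029385) was at 2.33. A prohibitin (AC217358.3_FG005), part of a scaffold of the inner membrane, was at 1.36, from 265 FPKM to 914 RPKM. The 1 lower member was a Tim17 family gene (GRMZM2G070978), at -1.30.

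In the list of respiratory complexes, 7 of 45 genes were higher and 0 were lower, with a median of 0.42 (0.21 to 0.53, percentile 100), against 13 of 45 higher as deposited. However, 5 of those 7 carry the names of cytochrome c oxidase subunits that the mitochondrial genome encodes, and reads from mitochondrial transcripts can fall on such copies. Among them were GRMZM2G450825 (subunit 1, at 1.35) and GRMZM2G109332 (subunit 2, at 1.28). Without the 12 genes with names of this kind, 2 of 33 were higher and the median was 0.22 (percentile 99.13). Those were a subunit 7 gene of the cytochrome b-c1 complex (GRMZM2G318346, 1.29) and the Rieske protein isp1 (GRMZM2G023194, 1.02). Pentatricopeptide repeat proteins, most of which process organelle RNA, had 0 of 18 genes past 2-fold in either direction after scaling and a median of 0.27 (0.10 to 0.49, percentile 88.88). As deposited, 3 of 22 were higher and the median was 0.50, and at a minimum level of 5 it was 0.64. This list took 24 genes by their descriptions, which 20161 of the 41406 genes lack, so it need not stand for the whole family.

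Glutathione S-transferases conjugate glutathione to reactive compounds. Their list had 11 of 21 genes higher and 0 lower, with a median of 1.04 (0.36 to 1.87, percentile 100). The median was 0.58 with no minimum level and 0.56 with a pseudocount of 5. The highest ratio among described genes at 10 or more in a library was that of gst42 (GRMZM2G025190), at 5.62 FPKM in the wild type and 346 RPKM in dek40, a log2 ratio of 5.29. GST4 (GRMZM2G132093) was at 4.46 and gst5 (GRMZM2G308687) at 2.34, while the abundant gst1 (GRMZM2G116273) was at 0.36. A further gene with the symbol gst41 (GRMZM2G097989) had no informative description, lay outside the list and was at 4.90. Peroxidases, catalases and superoxide dismutases had a median of 0.00 (-0.14 to 0.28, percentile 53.05) over 32 genes, against 0.39 as deposited with 6 higher and 1 lower. After scaling, Peroxidase 56 (GRMZM2G321839, 1.46) was higher and the catalase cat2 (GRMZM2G090568, -1.22) was lower.

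**Figure D2:**
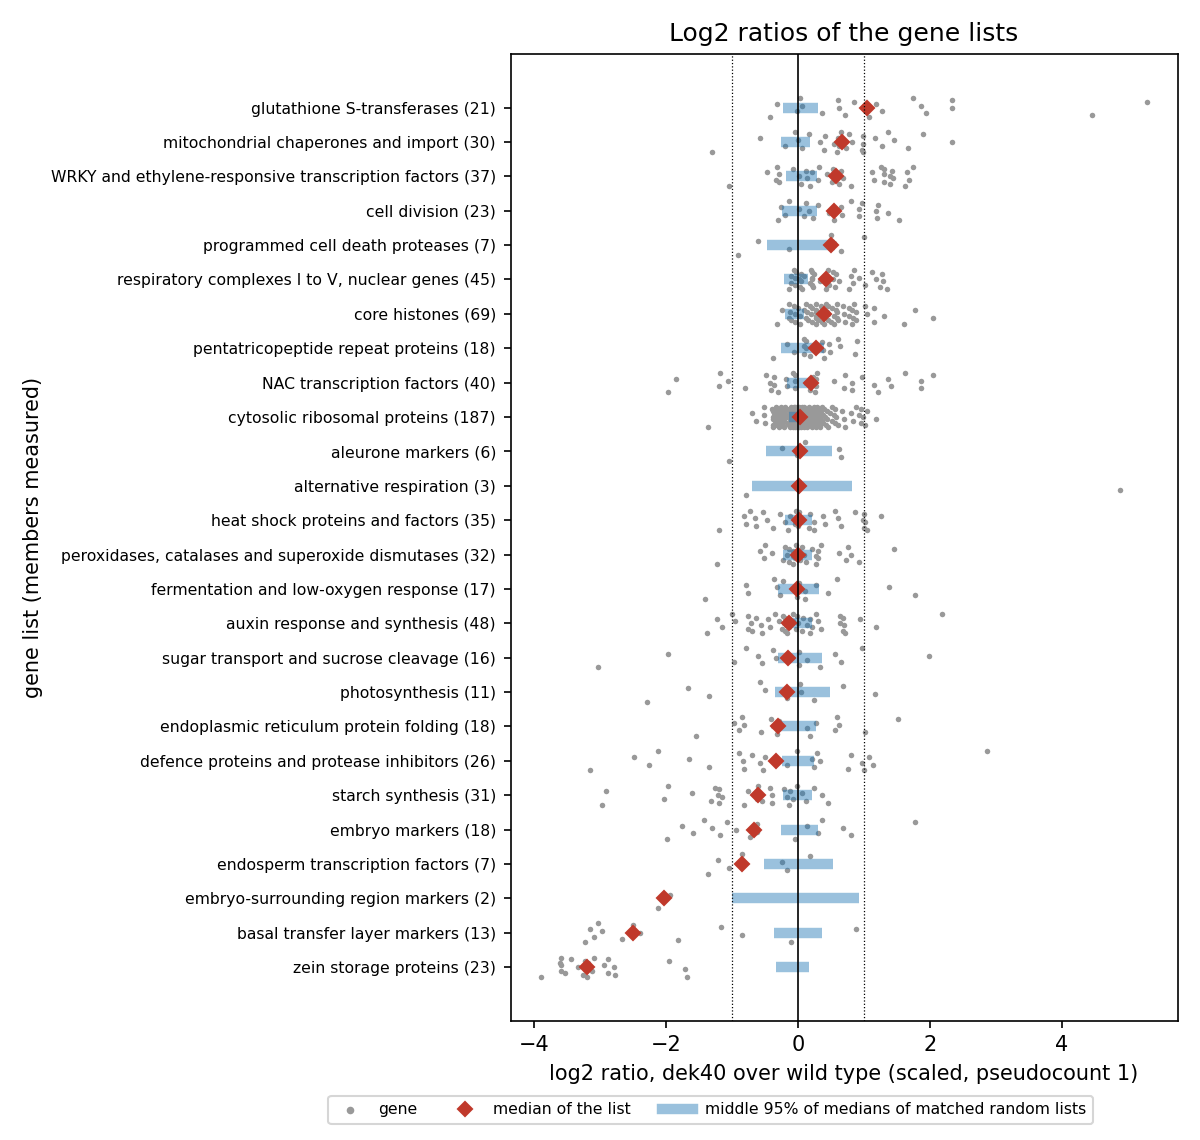
Log2 ratio (dek40 over wild type, scaled, pseudocount 1) of every measured member of the 26 gene lists (grey points), with the list median (red diamond) and the middle 95% of the medians of 10000 random lists matched on level (blue bar). The zein and basal transfer layer medians lie at -3.20 and -2.49, and that of the glutathione S-transferases at 1.04.

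In the cell division list 5 of 23 genes were higher and 0 were lower, with a median of 0.55 (0.12 to 0.93, percentile 99.99). As deposited, 11 of 23 were higher and the median was 0.94; with no minimum level it was 0.34 and with a pseudocount of 5 it was 0.36. The replication clamp genes pcna1 (GRMZM2G030523) and pcna2 (GRMZM2G108712) had log2 ratios of 1.53 and 1.22. The others were the replicative helicase subunits MCM6 (GRMZM2G021069, 1.20) and MCM3 (GRMZM2G100639, 1.19), and a cyclin A2 gene (GRMZM5G879536, 1.36). Core histones, which package newly made DNA, were higher in 8 of 69 cases and lower in 0, with a median of 0.40 (0.28 to 0.54, percentile 100), against 24 of 69 higher as deposited. A histone H3 gene (GRMZM2G145758) was at 21 FPKM and 120 RPKM, a log2 ratio of 2.04, while the most abundant H2A gene, his2a1 (GRMZM2G305046), was at -0.11. Histone genes are close copies, so the values of single members are uncertain. The 187 cytosolic ribosomal protein genes had a median of 0.04 (-0.01 to 0.09, percentile 98.64), against 0.46 as deposited with 14 higher and 0 lower. After scaling, a pair of S12 genes (GRMZM6G741620, 1.02, and GRMZM2G139900, 1.04) and an S24 gene (GRMZM2G029685, 1.19) were higher, and an L18A gene (GRMZM2G021877, -1.36) was lower.

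Among transcription factors of stress responses, WRKY and ethylene-responsive factors were higher in 14 of 37 cases and lower in 1 (GRMZM2G005207, -1.04), with a median of 0.58 (0.21 to 1.15, percentile 100). As deposited, 16 of 41 were higher and 0 lower. The scaled median was 0.27 with no minimum level and 0.23 with a pseudocount of 5. Most were at low levels, and the most abundant of the 14 was a WRKY gene (GRMZM2G449681) at 6.41 FPKM and 30.4 RPKM, a log2 ratio of 1.68. NAC factors had 8 of 40 genes higher, 5 lower and a median of 0.20 (-0.17 to 0.54, percentile 95.71), against 13 of 42 higher, 3 lower and a median of 0.60 as deposited. NAC126 (GRMZM2G018436) was at 2.04, and nac4 (GRMZM2G154182), the most abundant NAC gene, was at -1.85, from 705 FPKM to 260 RPKM. The programmed cell death proteases had a median of 0.50 (-0.91 to 1.00, percentile 96.16), which was 0.23 with a pseudocount of 5 and 0.25 with no minimum level. A type II metacaspase (GRMZM2G083016, 1.00) was the 1 higher gene of 7.

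Heat shock proteins and factors had a median of 0.01 (-0.15 to 0.38, percentile 51.08), with 4 of 35 higher and 1 lower, against 9 of 35 higher, 0 lower and a median of 0.36 as deposited. The higher ones were hsp82 (GRMZM5G833699, 1.26), an HSP90 activator gene (GRMZM2G038108, 1.04), the heat shock factor HSF6 (GRMZM2G059851, 1.01) and a class I small heat shock protein at a low level (GRMZM2G479260, 1.00). The lower one was a chloroplast small heat shock protein (GRMZM5G803365, -1.20). Endoplasmic reticulum folding genes had a median of -0.30 (-0.81 to 0.57, percentile 2.40) over 18 genes. The calreticulin crt2 (GRMZM2G358059, 1.02) and a protein disulfide isomerase (GRMZM2G106344, 1.51) were higher, and Derlin-2.2 (GRMZM2G112609), a factor in the disposal of misfolded proteins, was lower at -1.54. The chaperone bip1 (GRMZM2G114793) was at -0.96. Fermentation genes had a median of -0.01 (-0.32 to 0.27, percentile 46.13) over 17 genes. The pyruvate decarboxylase pdc3 (GRMZM2G087186, 1.38) and the hemoglobin gene named above were higher, hemoglobin 2 (GRMZM2G168898, -1.40) was lower, and the alcohol dehydrogenase adh1 (GRMZM2G442658) was at -0.79.

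Defence proteins and protease inhibitors had 6 of 26 genes lower and 3 higher, with a median of -0.33 (-0.83 to 0.33, percentile 0.22), against 5 of 27 lower, 8 higher and a median of 0.23 as deposited. The lower ones include betl10 and esr6, which are also the transfer layer and embryo-surrounding region markers named above. The chitinase chiB (GRMZM2G005633) was at 285 FPKM and 67.2 RPKM, a log2 ratio of -2.48. The higher ones were a Bowman-Birk trypsin inhibitor (GRMZM2G075315, 2.87), a thaumatin-like gene (GRMZM2G138419, 1.08) and a PR10 gene (GRMZM2G112488, 1.14). The auxin list had 3 of 48 genes lower and 2 higher, with a median of -0.13 (-0.24 to 0.08, percentile 4.06), against 2 of 49 lower and 7 higher as deposited. SAUR33 (GRMZM2G400156, 2.18) and SAUR11 (GRMZM2G425072, 1.18) were higher. Auxin-binding protein abp1 (GRMZM2G116204, -1.15), SAUR52 (GRMZM2G042429, -1.23) and an auxin-repressed gene (GRMZM2G073755, -1.37) were lower.

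Outside the lists, the lowest ratio among described genes at 10 or more in a library was that of a thioredoxin gene (GRMZM2G150091), at 136 FPKM in the wild type and 1.3 RPKM in dek40, a log2 ratio of -6.11 with a counting interval of -8.44 to -6.08. A subtilase family gene (GRMZM2G437435), which encodes a protease, was at 3.19 FPKM and 199 RPKM, a log2 ratio of 5.16. A pair of cytochrome P450 genes had log2 ratios of 4.17 (GRMZM2G087875) and 3.46 (GRMZM2G075244). The most abundant gene of both libraries, GRMZM2G005721, had no description and stood at 64418 FPKM and 71389 RPKM, with an implied length of at least 95 bp. With the values as deposited the medians of the photosynthesis, endoplasmic reticulum folding, fermentation, sugar transport and auxin lists lay above 0, at 0.24, 0.11, 0.40, 0.24 and 0.27, so their side of 0 rests on the scaling.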

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

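Recovered reads as a share of the implied totals, the counting-interval rule and lists without mistaken or doubtful members were chosen after the result was seen. The other alternatives were planned. The count of higher genes (1784) became 3139 with a pseudocount of 0.1, 514 with 5, 4282 with the values as deposited, 1152 at a minimum level of 5, and 177 at 4-fold. The count of lower genes (1406) became 2370, 558 and 771 under the first 3 of these, and 223 at 4-fold. Higher and lower counts were 1724 and 1445 with upper-quartile scaling and 1768 and 1412 with trimmed-mean scaling. They were 1672 and 1289 with the counting-interval rule. With no minimum level they stayed at 1784 and 1406. That is fixed by the pseudocount of 1, since a gene below 1 in both libraries cannot reach 2-fold. As deposited, 1784 of the 1784 higher genes and 771 of the 1406 lower genes kept their call. As deposited, the median was -2.78 for zeins, -1.64 for embryo-surrounding region markers, 0.78 for respiratory complexes, 1.08 for mitochondrial chaperones, 0.94 for cell division and 0.82 for histones. With the zeins left out of the scaling it was -1.82 for embryo-surrounding region markers, 0.64 for respiratory complexes and 0.63 for histones, and with a pseudocount of 5 it was -1.72 for the embryo-surrounding region. These shifts follow from the scaling factor or pseudocount itself. Recovered zein reads were 16.7% of the implied library total in the wild type and 3.22% in dek40. Recovered reads are lower bounds that sum to 86.5% and 86.3% of these totals over all genes. These shares therefore lie below those of the summed FPKM and RPKM partly for that reason. Of 215 list medians under an alternative, 195 stayed within the interval of the median and 20 moved. In 14 of the 215, from 7 lists, the median lay on the other side of 0, but in 0 cases for the 11 lists whose interval excludes 0 (for the embryo-surrounding region, the range of its 2 members). Of 875 single-gene values under the other pseudocounts and scalings, 190 lay outside the range that spans the counting interval and the main value. No paired analysis was possible because there was 1 library per genotype, and leaving out a replicate or splitting the samples otherwise was not possible either. Depth limits the genes with few reads.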

Other observations

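The gene groups in this and the next paragraph, and all tests below except that of the length of the zein genes, were chosen after the result was seen. Proteasome subunits had 4 of 38 genes higher and 0 lower in the library labelled dek40, with a median log2 ratio of 0.23 (0.08 to 0.60, percentile 99.53 among random lists), against 12 of 38 higher as deposited. A beta subunit gene (GRMZM2G124417) was at 7.27 FPKM in the wild type and 86.5 RPKM in dek40, a log2 ratio of 2.99. The others were alpha subunit genes, AC149828.2_FG002 at 1.39, GRMZM2G056870 at 1.00 and GRMZM2G080549 at 1.04. Chaperonin genes, which include subunits of the cytosolic complex that folds tubulin and actin, had 2 of 21 genes higher, with a median of 0.73 (0.39 to 0.78, percentile 100). They were CPN60-2 and GRMZM2G074790 (1.19), and 14 of 21 were higher as deposited. Of 15 tubulin genes 5 were higher, among them tua4 (GRMZM2G152466, 1.31), with a median of 0.86 (0.29 to 1.13, percentile 100), against 9 as deposited. Enzymes of the citric acid cycle and their isozymes had 5 of 19 genes higher and 0 lower, with a median of 0.68 (0.14 to 1.00, percentile 100), against 11 higher as deposited. An isocitrate dehydrogenase subunit (GRMZM2G025366) was at 4.01 FPKM and 41.3 RPKM, a log2 ratio of 2.67, and cytosolic malate dehydrogenase (GRMZM2G415359) was at 1.42. Glycolytic enzymes had 5 of 40 genes higher and 1 lower (9 of 41 and 0 as deposited), with a median of 0.18 (0.02 to 0.37, percentile 97.91), and the lower one was a pyruvate kinase (GRMZM2G152686, -1.40). The voltage-dependent anion channel gene vdac2 (GRMZM2G115049), a pore of the mitochondrial outer membrane, was at 69.7 FPKM and 691 RPKM, a log2 ratio of 2.87.

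Aquaporins had 6 of 16 genes lower and 1 higher, with a median of -0.90 (-1.29 to -0.18, percentile 0.00), against 4 lower and a median of -0.50 as deposited. The vacuolar aquaporin TIP3.1 (GRMZM2G037327) was at 2388 FPKM and 1043 RPKM, a log2 ratio of -1.61. The higher one, PIP2-4 (GRMZM2G154628, 2.09), rested on 1 wild-type read at the least. Trypsin and chymotrypsin inhibitors were lower in 5 of 7 cases and higher in 1 (the Bowman-Birk gene GRMZM2G075315, 2.87), with a median of -2.04 (-2.36 to 2.87, percentile 0.00). The inhibitor gene hag (GRMZM2G304548) was at 11143 FPKM and 3627 RPKM, a log2 ratio of -2.04. Lipid-transfer proteins parted, with 5 of 17 higher and 6 lower, a median of -0.54 (-1.39 to 1.09, percentile 0.03) and -0.19 as deposited. The aleurone gene AL-9 (GRMZM2G091054) was at 2607 FPKM and 7778 RPKM, a log2 ratio of 1.16, and another family member (GRMZM2G406552) was at -3.39.

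For the low storage and transfer layer transcripts, the higher of the zein and basal transfer layer medians over 5 scalings was -2.07. The scaling factors ran from 0.739 to 1.000, too close together to bring either median near 0. The choice among these scalings therefore does not explain the pattern, and other scalings were not tried. Other genes at 10 FPKM or more in the wild type were compared by implied length. Between the lower and upper quartiles of the zeins (479 to 756 bp), 1865 such genes had a median of -0.05. Between those of the transfer layer markers (255 to 499 bp), 2263 had one of -0.09. Implied lengths are lower bounds, so these genes need not match in true length. The alpha zeins GRMZM2G353268, fl4 and GRMZM2G059620 had implied lengths of 702, 351 and 234 bp. The comparison therefore cannot decide whether gene length plays a part, which stays open. A smaller share of endosperm in the sample would lower endosperm genes alike. The zein median lay -2.60 from the starch median with intervals apart (-3.44 to -2.87 and -1.19 to -0.17). However, the starch list was not restricted to genes of the endosperm, and 20 of its 31 genes stayed within 2-fold. Its most abundant members, sh1, bt2, sh2 and bt1, were at -1.97, -1.61, -1.26 and -2.03. The gap between the medians therefore cannot decide this explanation, which stays open. Slower endosperm development in dek40, which would leave cells dividing for longer, stays open as a hypothesis: the cell division median lay at percentile 99.99, but the hypothesis was formed after that value was seen, so it is no independent support. With 1 library of each genotype, a difference between the kernels or libraries other than the genotype stays open and was not tested.

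The high alternative oxidase transcript is another pattern to follow up. Counting error is argued against by the lower bound of the interval, 4.92. The family member most abundant in the wild type had a log2 ratio of -0.78, which argues against reads shared with that gene alone. Of 4 matched family genes, 3 reached a level of 1, and genes read in 1 library alone are not listed. Reads shared with another copy therefore stay open. A mitochondrial response in dek40 stays open as a hypothesis: mitochondrial chaperones and import lay at percentile 100, but this too was seen before the hypothesis was formed. The sample labels name dek40, and the series title and design text name dek41. Which of them was sequenced stays open. No gene matched the symbol dek41, and the kind of dek40 allele is not given. These gene-level values therefore hold no test of either mutation.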
